A study of Mus musculus with 14 samples.

How the data were processed

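RNA from whole mouse embryos at 4.5, 6.5, 7.5, 8.5, 9.5, 11.5 and 14.5 days post coitum (dpc) was measured on 2-colour cDNA arrays against 1 common reference, a pool of CD1 embryos of 18.5 dpc. Per the labels' protocols, total RNA was reverse transcribed with amino-allyl nucleotides, coupled to Alexa Fluor 555 or 647 and hybridised in duplicate with a dye swap, and the slides were scanned on a GenePix 4000A. Each stage therefore has 2 arrays, 1 with the embryo in Alexa 647 and 1 with the embryo in Alexa 555. The arrays of a stage were taken as technical repeats, so a stage counted as 1 sample and p-values measure the spread between stages. Nothing in the labels says whether the embryos of a stage came from several litters.

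The deposited values are log ratios of the 2 channels, 1 per spot, taken here as log2; the log base, the background correction, the normalization and any filter on poor spots are not given in the sources used here. Spot values ran from -5.36 to 3.57. The deposited log2 values are not centred: in order of stage, the medians of all spots were -0.14, -1.015, -1.23, -1.165, -0.595, -1.28 and -0.785 with the embryo in Alexa 647, and -0.915, -0.375, -0.57, -0.83, 0.01, 0.085 and -0.4 with the embryo in Alexa 555. Which channel is the numerator, and whether swapped arrays had been turned, is not given either. Per the labels, Alexa 647 is channel 1 on all 14 arrays. The deposited log2 ratios were therefore taken as Alexa 647 over Alexa 555, and the 7 arrays with the embryo in Alexa 555 changed sign before averaging. This direction is an assumption that rests on the order of the channels alone. It was chosen after the correlations of swap partners had been seen and before any counts of genes were compared. Values with no change of sign are given beside the main ones for most counts and for some genes only. The ratio control probes do not decide it. The mean difference between their even-numbered and odd-numbered members was 3.18 to 3.90 on the arrays with the embryo in Alexa 647, 3.15 on the 7.5 dpc array with the embryo in Alexa 555 and -0.24 to 1.21 on the other 6. It would keep its sign in unturned values if the control RNAs went with the dyes, and in turned values if they went with the samples, and which of these was done is not given in the sources used here.

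Each array holds 288 spots, of which 201 belong to 67 gene probes with 3 spots each, 33 are empty, 30 belong to 10 calibration probes and 24 to 8 ratio control probes. Spots of a probe were averaged. Probe identifiers were matched without versions to the RefSeq gene table of assembly GRCm38.p6, which was used for names and for gene order only. This named 41 probes by RefSeq accession and 1 by a clone name listed as a synonym, and the other 25 keep their identifier. The synonym probe and an accession probe both stand for Dgcr8 and were averaged, although their values correlated weakly over the 14 arrays (Pearson r = 0.317, Spearman rho = 0.270). That left 66 genes for testing, 41 of them named. No value was missing.

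The 5th to 95th percentile of the empty spots on an array was used as the range in which a ratio is not told apart from spots with no gene. No spot intensities were used, so signal over background is known only in this indirect way, and the number of arrays limits the precision. Where this range spans 0, an expressed gene at the level of the reference also lies inside it. That held on all arrays with the embryo in Alexa 555 and on the 4.5 dpc array in Alexa 647. Tests were made with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p of 0.05) in R 4.3.3 on the 7 stage averages; names, lists and plots were made with Python 3.11.15. The 4 limma comparisons were the slope per day over the stages, the late stages (9.5, 11.5 and 14.5 dpc) against the early stages (4.5 to 8.5 dpc), the stages of pharyngeal arch development (8.5, 9.5 and 11.5 dpc) against the others, and the mean of the stages against the reference. The last leaves out the spread of the reference itself, which is 1 sample.

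Gene lists were tested along the stages with camera (preset correlation 0.01, with an estimated correlation beside it) and fry where at least 4 members were measured. The lists were the 22q11 deleted region (18 of 41 genes measured), its flanking regions (5 of 51), pharyngeal and heart regulators (14 of 82), the retinoic acid pathway (3 of 18), cell cycle and replication (1 of 22), housekeeping genes (0 of 22), extraembryonic and maternal markers (0 of 21) and neural markers (0 of 18). Measured here means matched by name. The series design text counts 39 orthologues of 22q11 genes and 29 genes elsewhere. Some of the 25 probes without a name therefore belong to 22q11 and some to genes elsewhere. All 25 are in no list or region test, so any of the lists may lack measured members. The 18 measured genes of the deleted region were compared with the 18 named genes outside both region lists by 1e+05 permutations of the gene labels, for the median slope, the median level and the correlation of stage profiles. Genes off the reference at a stage, and steps between neighbouring stages, had no test: the first needed a log2 ratio of at least 1 on both arrays, the second a step of at least 1 in the average and 0.5 on each array.

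The genes named in the text were chosen by a fixed rule. It takes up to 12 genes per direction past the threshold, ranked by effect, in each limma comparison, filled up to 10 by the smallest p where fewer passed. It adds up to 3 genes per direction at each stage in the untested results, a fixed set of 22q11 genes where measured, and the members of small lists. At most 2 identifiers without a name are printed per direction. A few genes that the rule takes are not reported here by name; they stay in every test, count and list. The stage groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other centring and scaling, 1 dye orientation alone, models of all 14 arrays, other summaries of spots, other codings of stage, exact permutations, and leaving out each array or stage. Added after the data had been seen were the settings with no change of sign, centring on the calibration spots, centred arrays of the Alexa 647 orientation, that orientation without 4.5 dpc, a block for the 6.5 to 8.5 dpc stages and the removal of genes at the level of the empty spots.

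The limma steps were tested on simulated data with the observed spread of the 66 genes, with 200 changed genes per size. For the slope, 17% of genes changed by 0.2 per day and 90% of those changed by 0.4 were recovered. For early against late stages, 4% were recovered at a change of 1 and 80% at 2. For the pharyngeal stages these shares were 6.5% at 1 and 79% at 2, and for the mean against the reference 5% at 0.5 and 79% at 1.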

Results

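The expression of genes orthologous to human 22q11, the chromosome region deleted in DiGeorge syndrome, and of developmental genes mapping elsewhere was followed in whole mouse embryos over 7 stages from 4.5 to 14.5 dpc. The question was whether the 22q11 genes are regulated together, or alike with other genes, while the pharynx forms. Each of the 7 stages was 1 sample, read on 2 arrays with the dyes exchanged, against a pool of 18.5 dpc embryos. Of the 66 genes measured, 18 named genes lie in the deleted region, 5 in its flanks and 18 elsewhere, and 25 carry only an identifier. The series design text counts 39 orthologues of 22q11 genes and 29 genes elsewhere, so some of these 25 belong to each group. All 25 are left out of the list and region tests. All signed values are log2 ratios of embryo over reference in an assumed direction, with Alexa 647 as numerator in the deposited values. The labels give the dyes but not the numerator, so higher and lower hold only under that assumption.

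The number of genes set apart from empty spots differed between the dye orientations. With the embryo in Alexa 647, between 17 and 34 of the 66 genes lay inside the range of the empty spots on the 6.5 to 14.5 dpc arrays, and 61 did on the 4.5 dpc array. With the embryo in Alexa 555, between 48 and 64 genes lay inside it. There the range spanned 0 on every array, with lower ends of -2.692 to -0.576 and upper ends of 0.226 to 2.142. A gene at the level of the reference also lies inside such a range, so the counts depend on where the empty spots lie. Vpreb1, Vpreb2, Hoxb1 and Fgf8 lay inside it on all 14 arrays, and only 12 genes lay outside it on at least 8 arrays. Repeat spots of a probe had an intraclass correlation of 0.82 to 0.93 on the arrays with the embryo in Alexa 647. In Alexa 555 it was 0.36 at 6.5 dpc, 0.39 at 8.5 dpc and 0.65 to 0.87 at the other stages. The stage averages of 6.5 and 8.5 dpc therefore each include a noisier array.

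**Figure D1:**
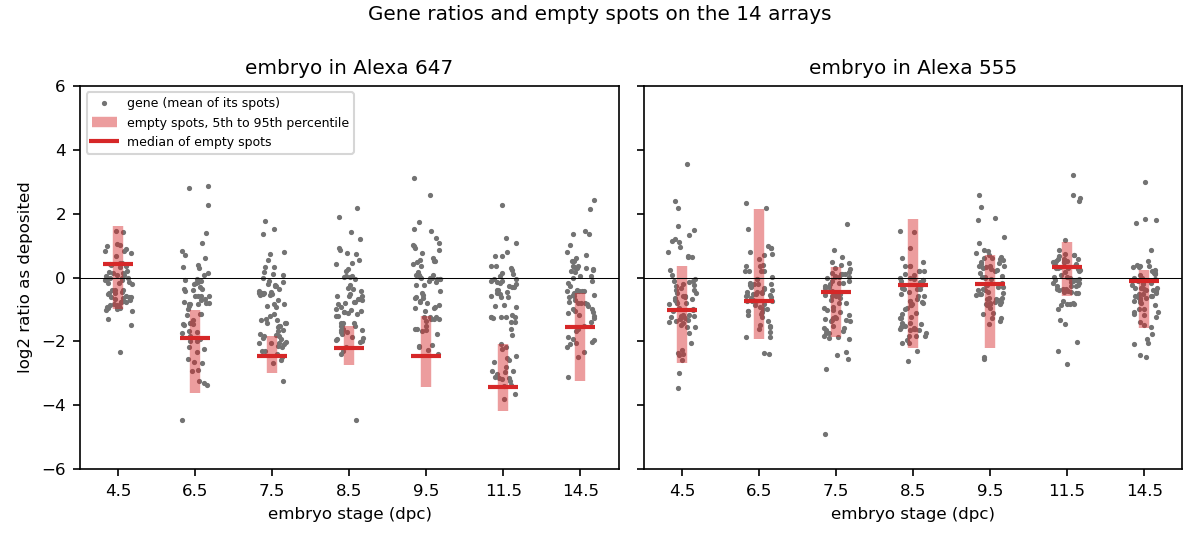
Log2 ratios as deposited (vertical axis) of the 66 genes on the 14 arrays by embryo stage in dpc (horizontal axis), with the embryo in Alexa 647 on the left and in Alexa 555 on the right. Each point is 1 gene, each bar the 5th to 95th percentile of the empty spots and each dash their median; on the left, from 6.5 dpc on, the empty spots have medians of -3.44 to -1.56 and at 4.5 dpc of 0.43.

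The 2 arrays of a stage correlated weakly over the 66 genes, which are not independent replicates. After the change of sign Pearson's r was -0.04 at 4.5 dpc, 0.38 at 7.5 dpc and had a median of 0.09 over the stages; without it the signs are opposite. Hand2, Aldh1a2, Crkl, Serpind1 and Arvcf were among the 24 genes with a ratio outside the range of the empty spots on both arrays of at least 1 stage. Over these 41 gene and stage pairs r was 0.48, and 0.41 over the 40 pairs without Hand2, against 0.06 over the other pairs. The value over the 41 pairs was larger than in permutations of the genes within stages (two-sided permutation p = 0.0014, 10000 permutations, a test chosen after the pairs had been seen). The pairs were picked by their own ratios, which enlarges a correlation. The relation was not even over the stages. At 4.5 to 8.5 dpc r was 0.80 over 16 pairs, 10 of them at 7.5 dpc, and 14 had the same sign on both arrays after the change of sign. At 9.5 to 14.5 dpc r was 0.12 over 25 pairs, of which 9 had the same and 16 the opposite sign, among them all 6 pairs at 14.5 dpc. The pairs therefore do not settle the direction, which rests on the order of the dye channels in the labels alone.

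**Figure D2:**
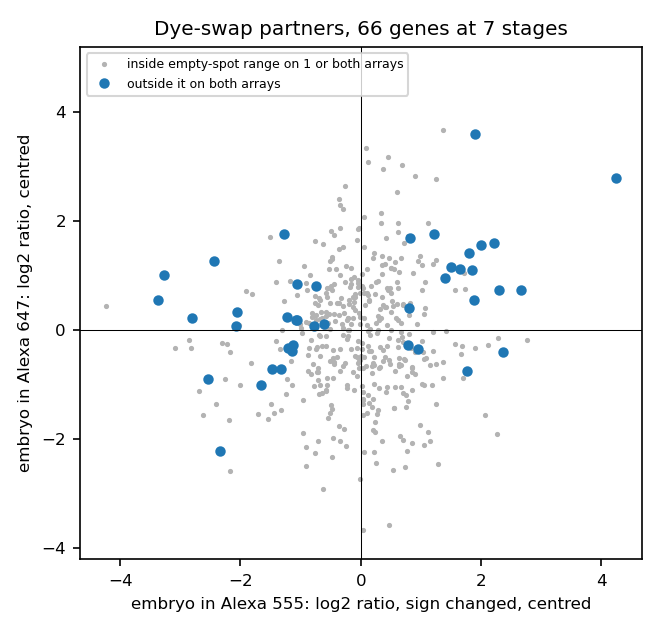
Log2 ratio of each gene at each stage on the array with the embryo in Alexa 555 after the change of sign (horizontal axis) and with the embryo in Alexa 647 (vertical axis), each array centred on the median of its genes. Blue points are the 41 pairs outside the range of the empty spots on both arrays, with r = 0.48 and the same sign in 23 of them, and grey points are the other pairs.

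Aldh1a2, the enzyme that makes retinoic acid in the early embryo, lay above the late-gestation reference over the stages, with a mean log2 ratio of 1.33 ± 0.25 (SE, n = 7 stages). Its stage averages were above 0 at 7 of 7 stages, as were 4 of its 7 single values in Alexa 647 and 7 of 7 in Alexa 555. Crabp1, a retinoic acid binding protein, was at 1.00 ± 0.24, with 7 of 7 averages above 0, 5 of 7 values in Alexa 647 and 7 of 7 in Alexa 555. Hand2, a transcription factor of the heart and pharyngeal arches, was at 1.03 ± 0.38, Tssk1, a testis-specific kinase, at 0.73 ± 0.26 and Mrpl40, a protein of the mitochondrial ribosome, at 0.65 ± 0.24. Serpind1, the plasma thrombin inhibitor heparin cofactor II, lay below the reference at -1.24 ± 0.27, with 7 of 7 averages below 0. Its mean was -2.22 in Alexa 647 but -0.27 in Alexa 555, where 3 of 7 values were above 0.

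In all, 16 of 66 genes differed from the reference in limma at a Benjamini-Hochberg adjusted p of 0.05, 6 higher and 10 lower. Leaving out 1 array leaves its stage with 1 dye orientation, so a shift between the orientations then counts as spread between stages. Leaving out a whole stage keeps the pairs and gave 9 to 15 genes. With 1 array left out the count ranged from 3 to 19. It was 3 without the Alexa 647 array of 7.5 or of 8.5 dpc or the Alexa 555 array of 11.5 dpc, 4, 5, 6 and 7 without the Alexa 647 arrays of 6.5, 4.5, 14.5 and 9.5 dpc, 9 without the 8.5 or the 9.5 dpc stage and 10 without the Alexa 555 array of 14.5 dpc. Over the 21 settings that leave out 1 array or 1 stage, Aldh1a2 and Crabp1 passed in 21, Serpind1 in 19, Hand2 in 6, Tssk1 in 5 and Mrpl40 in 2. The adjusted p was 0.000792 for Aldh1a2, 0.002 for Serpind1, 0.00493 for Crabp1 and 0.0487 for Hand2 and Mrpl40. Of the 18 genes of the deleted region, Tssk1 and Mrpl40 were higher, Serpind1 and Tssk2 (-0.82 ± 0.25) lower, and 14 did not pass; adjusted over the list alone, 2 passed. Of the 14 pharyngeal and heart regulators, 1 was higher, Hand2, 3 were lower, among them Shh (-0.73 ± 0.25) and Hoxb1 (-0.70 ± 0.25), and 10 did not pass; adjusted over the list alone, 6 passed. In the flanking list Vpreb1 (-0.98 ± 0.25) and Vpreb2 (-0.80 ± 0.26), parts of the receptor of B cell precursors, were lower and 3 did not pass, with 2 calls adjusted over the list alone. Of the 3 retinoic acid genes Aldh1a2 and Crabp1 were higher, also adjusted over the list alone, and Rxra, a nuclear retinoid receptor, did not pass (0.11 ± 0.27), but was lower on the Alexa 647 arrays alone (-1.76) and higher on the Alexa 555 arrays alone (1.99). Among genes without a name, AF098068 was higher (0.71 ± 0.23), and BC013709 (-1.05 ± 0.27) and X99713 (-1.02 ± 0.26) were lower. X99713 lay inside the range of the empty spots on 10 of 14 arrays, 6 of them in Alexa 647, and BC013709 on 6 of 14. Of the lower genes, Vpreb1, Vpreb2 and Hoxb1 lay inside the range of the empty spots on all 14 arrays and Shh and Tssk2 on 12 of 14. Their values are therefore not told apart from spots with no gene and are not read as lower expression. Of the higher genes, Crabp1, Tssk1, Mrpl40 and AF098068 lay inside this range on 8 of 14 arrays, 7 of them in Alexa 555, and Hand2 on 9 of 14. Their Alexa 555 values are thus not told apart from spots with no gene at all or most stages, and Alexa 647 arrays alone called 0 genes as higher. With these arrays centred 11 were called higher, among them Crabp1, Tssk1, Mrpl40 and AF098068 but not Aldh1a2 or Hand2. Without the genes inside the range of the empty spots on at least 7 arrays, 12 genes were tested and 4 passed, Aldh1a2 higher and Serpind1 and 2 without a name lower. This keeps genes by the same ratios that are then tested against 0, so it is not an independent test.

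Ranbp1, the only gene matched by name from the cell cycle list, did not pass (0.15 ± 0.24). The deleted region's Dgcr2 (0.12 ± 0.26), Dgcr8 (-0.24 ± 0.24), Crkl (0.31 ± 0.26), Arvcf (0.33 ± 0.25), Cldn5 (-0.26 ± 0.27), Prodh (-0.20 ± 0.27), Ufd1 (0.49 ± 0.25) and Snap29 (-0.56 ± 0.25) did not pass either. Aldh1a2, Hand2, Crabp1, Tssk1 and Mrpl40 had positive means in both orientations, from 0.34 to 0.80 with the embryo in Alexa 647 and from 0.57 to 2.32 in Alexa 555. Vpreb1, Vpreb2, Tssk2, Shh and Hoxb1 were lower on the Alexa 647 arrays alone and had means of 0.24 to 0.51 in Alexa 555. Alexa 647 arrays alone gave 0 higher and 35 lower genes, Alexa 555 arrays alone 7 higher and 0 lower, and no change of sign 0 higher and 33 lower, with Aldh1a2 at -0.99. With arrays centred on the median gene, Alexa 647 alone gave 11 higher and 14 lower and no change of sign 10 higher and 11 lower, so the one-sided counts depend on the level of the arrays. The median gene lay at -0.10 averaged over the stages, and with arrays centred on it 7 genes were higher and 8 lower.

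Between the early and the late stages, Hand2 fell by 2.44 ± 0.68 (SE) on the log2 scale, from a mean of 2.07 ± 1.13 (SD, n = 4 stages) to -0.37 ± 1.79 (SD, n = 3 stages). Of the genes without a name, BC013709 fell by 1.48 ± 0.42 and M35523 rose by 1.64 ± 0.47. The fall of Hand2 had a like size in both orientations, -2.27 with the embryo in Alexa 647 and -2.61 in Alexa 555, though it passed in neither alone. The orientations differed on where it lies. At 9.5 dpc, counted as late, Hand2 was at 3.11 in Alexa 647 and at 0.29 in Alexa 555, where 6 of 7 values lay inside the range of the empty spots. At 11.5 and 14.5 dpc, the stages of its lowest values, both arrays of Hand2 lay inside that range, at -2.51 and -2.49 in Alexa 647. Its low late level and the size of the fall are therefore not read as expression. M35523 lay inside that range on 10 and BC013709 on 6 of 14 arrays.

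In all, 4 of 66 genes passed in limma, 1 higher and 3 lower, with a Benjamini-Hochberg adjusted p of 0.0423 for Hand2, BC013709 and M35523. The count was 0 without any 1 of 8 arrays, those of 4.5, 6.5, 7.5, 9.5 or 11.5 dpc in Alexa 555 and of 4.5, 7.5 or 14.5 dpc in Alexa 647, and without the 7.5, the 11.5 or the 14.5 dpc stage. It was 1 without the 8.5 dpc array in Alexa 555, and 2 without the Alexa 647 array of 8.5 or 9.5 dpc or the 6.5, 8.5 or 9.5 dpc stage. Hand2 passed in 10 of the 21 settings that leave out 1 array or 1 stage, BC013709 in 4 and M35523 in 3. In the settings without 1 array, a shift between the orientations again counts as spread between stages. Of the 14 pharyngeal and heart regulators 2 fell and 12 did not pass, and adjusted over the list alone the count was also 2. None of the 18 genes of the deleted region, the 5 flanking genes, the 3 retinoic acid genes or Ranbp1 (0.67 ± 0.42) passed, over all genes or adjusted over the list alone. These lists hold genes matched by name only, so a called gene without a name, such as M35523, could still be a member. The nearest among the genes with a name were Prodh, proline dehydrogenase, at -1.24 ± 0.46 (adjusted p = 0.174), Shh at -1.13 ± 0.43 (adjusted p = 0.174) and Foxc1, a forkhead gene of the arches and heart, at 1.03 ± 0.46 (adjusted p = 0.302). Prodh lay inside the range of the empty spots on 10, Shh on 12 and Foxc1 on 11 of 14 arrays. With no change of sign Shh turned, from an early mean of -1.51 to a late mean of -0.82. Prodh then went from -0.65 to -1.10 and Foxc1 from -0.77 to -0.22, so this order rests on the assumed direction. Crkl was at 0.80 ± 0.49, Cldn5 at -0.78 ± 0.52, Aldh1a2 at -0.87 ± 0.46, Crabp1 at 0.73 ± 0.41, Snap29 at -0.49 ± 0.48, Arvcf at -0.48 ± 0.47, Rxra at 0.33 ± 0.53, Dgcr2 at 0.15 ± 0.53, Dgcr8 at -0.12 ± 0.44 and Ufd1 at -0.01 ± 0.48.

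Arrays with the embryo in Alexa 647 alone gave 0 genes, with Crabp1 nearest at 2.36 ± 0.47 (limma, adjusted p = 0.0593), where Alexa 555 gave it the opposite sign (-0.90 ± 0.44), and Alexa 555 alone gave 5 lower genes, among them Shh (-1.81 ± 0.48). With no change of sign 2 genes passed, Crabp1 at 1.63 and 1 without a name, and Hand2 stood at 0.17. Arrays of 6.5, 7.5 and 8.5 dpc with the embryo in Alexa 555 correlated with each other at 0.08 to 0.49 over all spots, those of the other 4 stages at 0.28 to 0.60, and the 2 clusters at -0.13 to 0.09. The first cluster holds early stages only, so early and late stages can be compared within the second alone, where 4.5 dpc is the only early stage. An exact permutation test over the 35 splits of the stages left 0 after adjustment, which says little, since its smallest p is 0.0286 and at least 38 of the 66 genes would have to reach it.

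**Figure D3:**
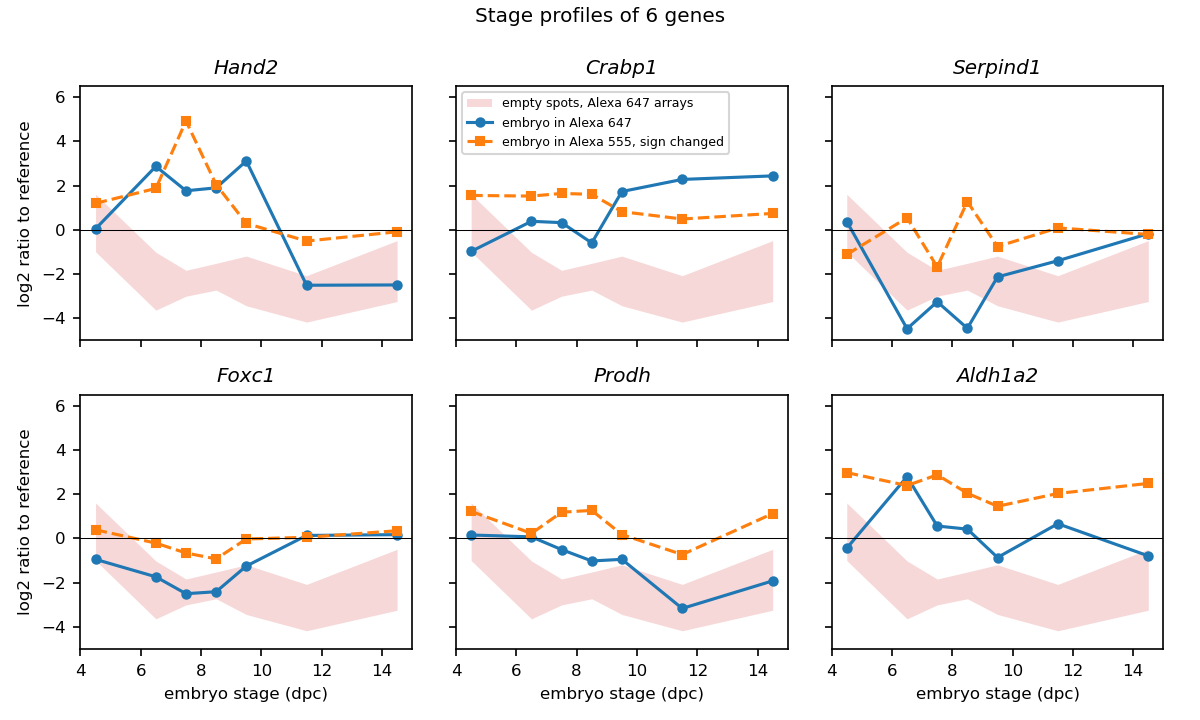
Log2 ratio to the reference (vertical axis) of 6 genes by embryo stage in dpc (horizontal axis), with circles for the array with the embryo in Alexa 647, squares for the array in Alexa 555 after the change of sign, and the 5th to 95th percentile of the empty spots on the Alexa 647 arrays shaded. Hand2 lies at 3.11 at 9.5 dpc and at -2.51, inside the shaded range, at 11.5 dpc in Alexa 647, where Serpind1 lies at 0.37 at 4.5 dpc, -4.47 at 6.5 dpc and -0.18 at 14.5 dpc, with 0.54 at 6.5 dpc in Alexa 555.

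Along the stages as a line, no gene passed. Hand2 had a slope of -0.37 ± 0.11 per day (SE, n = 7 stages) and Prodh of -0.17 ± 0.08. Crabp1 had a slope of 0.12 ± 0.07, with opposite signs in Alexa 647 (0.36) and Alexa 555 (-0.12), and Ranbp1, a regulator of nuclear transport, of 0.11 ± 0.07. Limma gave 0 genes past a Benjamini-Hochberg adjusted p of 0.05 and 4 at an unadjusted p under 0.05, with the lowest adjusted p 0.217 for Hand2. The exact permutation of Spearman's correlation also gave 0. With no change of sign limma gave 0 genes too, with 2 at an unadjusted p under 0.05. The slopes of Hand2, -0.44 in Alexa 647 and -0.30 in Alexa 555, largely cancel there, so its rank rests on the assumed direction. Without the 4.5 dpc stage 2 genes passed, among them Hand2 (-0.61 per day). Hand2 also passed without the 9.5 dpc stage, without the 9.5 dpc array in Alexa 647 and without the 4.5 dpc array in Alexa 647, and Prodh (-0.30 per day) without the 14.5 dpc array in Alexa 555.

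The gene lists did not set themselves apart along the stages. The 14 pharyngeal and heart regulators had a median slope of -0.06 per day, with 0 genes past the threshold and 1, Hand2, adjusted over the list alone. The 18 genes of the deleted region had a median slope of -0.02, with 8 slopes above 0, and the 5 flanking genes of -0.06, and in both lists 0 genes passed, also adjusted over the list alone. Camera gave an adjusted p of 0.376 for each of the 3 lists, and 0.561 with an estimated correlation. Fry, which sets a list against no slope and not against other genes, gave adjusted p-values of 0.523 to 0.779. For the deleted region camera's direction was up against the other genes although its median and mean slope were below 0. With no change of sign this direction was down, and the median slope of the pharyngeal and heart regulators was 0.05.

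The named genes of the deleted region were not told apart from the named genes elsewhere. Their median slope was -0.02 per day against -0.06 for the 18 named genes outside, a difference of 0.04 (two-sided permutation p = 0.164). With no change of sign the order reversed, with 0.009 against 0.046 and a difference of -0.037 (two-sided permutation p = 0.394). In the assumed direction their median level was -0.07 against -0.25, a difference of 0.18 (two-sided permutation p = 0.282). Stage profiles of the 18 deleted-region genes correlated with each other at a mean r of 0.099 and rho of 0.098, those of the 18 others at an r of 0.098, and profiles between the sets at 0.061. The excess of the within-region value over the value between sets was 0.04 (two-sided permutation p = 0.543). Benjamini-Hochberg adjusted over these 3 permutation tests, the p-values were 0.423, 0.423 and 0.543, and genes are not independent replicates. What size of difference these tests, or the list tests above, could detect was not simulated. The 2 arrays of a stage correlated weakly, and 54 of the genes tested lay inside the range of the empty spots on at least 7 arrays. The lack of a difference therefore does not show that the sets are regulated alike, or that the region's genes vary independently.

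At the stages of pharyngeal arch development, Crkl, an adaptor protein of growth factor signalling in the deleted region, stood 1.35 ± 0.46 (SE) above its mean at the other stages, and Tssk1 stood at -1.28 ± 0.48. Crkl stood at 0.84 in Alexa 647 and 1.87 in Alexa 555, so with no change of sign it turned to -0.52, and Tssk1 came to -0.10. Edn1, a peptide that patterns the arches, stood at -0.97 ± 0.47, Hoxb1 at -0.88 ± 0.48, Shh at -0.85 ± 0.49 and Sema3c, a guidance cue of the cardiac outflow tract, at -0.80 ± 0.45. With no change of sign Edn1 (0.52), Hoxb1 (0.61) and Shh (0.09) turned too. None of these passed, and Hoxb1 lay inside the range of the empty spots on 14 and Edn1 and Shh on 12 of 14 arrays. Limma gave 0 genes past a Benjamini-Hochberg adjusted p of 0.05 and 2 at an unadjusted p under 0.05, Crkl and Tssk1, both with an adjusted p of 0.431. The exact permutation test gave 0 too, but with 35 splits at least 38 genes would have to reach its smallest p for any to pass, so it adds nothing. In each of the 5 lists with a measured member 0 genes passed, also adjusted over the list alone.

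At single stages there is no test, and only the arrays of a stage can be set side by side. Hand2 was at least 2-fold above the reference on both arrays at 6.5, 7.5 and 8.5 dpc, with averages of 2.37, 3.34 and 1.97. Aldh1a2 was so at 6.5 dpc (2.59), Usp18, an interferon-induced protease, at 7.5 dpc (1.39), Txnrd2 at 8.5 dpc, Mrpl40 at 9.5 dpc (1.09) and Tssk1 at 14.5 dpc (1.48). Serpind1 was at least 2-fold below it on both arrays at 7.5 dpc (-2.47) and Cldn5, a tight junction protein, at 11.5 dpc (-1.20). Of these Aldh1a2 at 6.5 dpc, Hand2 and Serpind1 at 7.5 dpc and Cldn5 at 11.5 dpc lay outside the range of the empty spots on both arrays, and the others on the Alexa 647 array alone. In total 23 gene and stage pairs met this, 11 higher and 12 lower, where 17.2 would if the 2 arrays were independent of each other, and 5 of the 23 lay outside that range on both arrays. With no change of sign there were 47, 1 higher and 46 lower, and with arrays centred too 14, 5 higher and 9 lower.

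Between neighbouring stages, 56 steps of at least 2-fold went the same way on both arrays, 27 up and 29 down. In 14 of them all 4 array values lay inside the range of the empty spots, in 0 all 4 lay outside it, and in 13 both Alexa 647 values lay outside it. Among these 13, Ufd1, a factor of protein degradation, stepped by 1.64 from 7.5 to 8.5 dpc, Txnrd2 by -1.28 from 8.5 to 9.5 dpc, Aldh1a2 by 1.05 from 9.5 to 11.5 dpc and Tssk1 by 2.26 from 11.5 to 14.5 dpc. The Alexa 647 value of 1 of the 2 stages lay inside the range for the other steps named here. These were Dgcr2 (2.38) and Arvcf, a catenin (1.75), from 6.5 to 7.5 dpc, Rxra (1.74) from 8.5 to 9.5 dpc, Hand2 (-3.21) and Usp18 (-2.66) from 9.5 to 11.5 dpc, and Usp18 (2.45) and Crkl (-1.73) from 11.5 to 14.5 dpc. From 4.5 to 6.5 dpc, where the median of the empty spots on the Alexa 647 arrays went from 0.43 to -1.89, 18 steps met the rule and 0 had both Alexa 647 values outside the range, so none is read as a change of a gene. With no change of sign 38 steps met the rule. How many steps 2 unrelated arrays per stage would give was not worked out, so the 56 are not read as an excess.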

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

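Settings with no change of sign, on calibration spots, on centred Alexa 647 arrays, on Alexa 647 without 4.5 dpc, with the 6.5 to 8.5 dpc block and without genes at the level of the empty spots were chosen after seeing the data. A turn of sign is listed for genes named in that comparison that passed in the main or the other setting. The arrays carry no replicate numbers that pair them, and taking the dye orientation as a replicate block gave 0, 4, 0 and 15 genes for the slope, early against late, the pharyngeal stages and the mean against the reference. Centring on housekeeping genes was not run, since 0 were matched by name. Dropping genes within 0.5 of 0 removed none and no value was missing, so both of these filters are void. When 1 array of a stage is left out, the other is assumed to vary like the averages. A shift between the orientations then counts as spread between stages. Signal over background limits the rest. The cause of the differences between settings was not tested, except that fewer genes (12) were tested without those at the level of the empty spots and that the block leaves 1 early stage.

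The count of 0 at the pharyngeal stages held in every setting run, where exact permutation could hardly give another, and the slope's 0 in all but those given here. Leaving out an array or a stage gave 0 to 2 genes for the slope, with 1 without the 9.5 dpc array in Alexa 647, the 14.5 dpc array in Alexa 555, the 4.5 dpc array in Alexa 647 or the 9.5 dpc stage, and 2 without the 4.5 dpc stage; Alexa 647 alone without 4.5 dpc gave 1. For early against late, 4 genes became 0 with Alexa 647 alone, as deposited or centred, with exact permutation, no change of sign and centred arrays, calibration spots or the block. The 0 of the block, whose early arm is 4.5 dpc alone, and that of exact permutation, where at least 38 genes would have to reach the smallest p, say nothing of the call. The 4 genes became 1 with a random block and dye term, robust eBayes, 8.5 dpc counted late or without genes at the level of the empty spots, and 2 with the median of spots or no change of sign. Leaving out an array or a stage gave 0 to 5. It gave 0 without the Alexa 555 arrays of 4.5, 6.5, 7.5, 9.5 or 11.5 dpc, the Alexa 647 arrays of 4.5, 7.5 or 14.5 dpc, or the 7.5, 11.5 or 14.5 dpc stage. It gave 1 without the 8.5 dpc array in Alexa 555, and 2 without the Alexa 647 arrays of 8.5 or 9.5 dpc or the 6.5, 8.5 or 9.5 dpc stage.

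For the mean against the reference, 16 genes became 9 with scaled arrays (3 higher), 7 with Alexa 555 alone, 35 with Alexa 647 alone, 25 with it centred (11 higher), 40 with it without 4.5 dpc (3 higher), 33 with no change of sign and 4 without genes at the level of the empty spots. Calibration spots gave 11 (5 higher), and no change of sign with centred arrays 21 (10 higher). Leaving out an array or a stage gave 3 to 19. It gave 3 without the Alexa 647 arrays of 7.5 or 8.5 dpc or the 11.5 dpc array in Alexa 555, 4, 5, 6 and 7 without the Alexa 647 arrays of 6.5, 4.5, 14.5 and 9.5 dpc, 9 without the 8.5 or the 9.5 dpc stage and 10 without the 14.5 dpc array in Alexa 555. The 23 pairs off the reference became 64 at 1.5-fold, 105 by the mean alone, 47 with no change of sign and 14 with that and centred arrays. The 56 steps became 98 at 1.5-fold, 94 by the mean alone and 34 with no change of sign and centred arrays. The median partner correlation of 0.0939 became -0.0939 with no change of sign.

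Signs turned as follows. In early against late with no change of sign, Hand2 was 0.17, BC013709 1.03 and XM_127583 2.01, and with centred arrays too BC013709 was 0.71; of the 4 genes called, 3 and 2 turned in these settings. In the mean against the reference, Alexa 555 alone gave Vpreb1 0.24, Tssk2 0.51, Vpreb2 0.38, Shh 0.49 and Hoxb1 0.51. With no change of sign, Aldh1a2 was -0.99, Hand2 -0.36, Crabp1 -0.20, AF098068 -0.27, Crkl -0.93 and Rxra -1.87, and with centred arrays too Aldh1a2 was -0.43, BC013709 0.13, X99713 0.20 and Rxra -1.31. Of the 16 genes called, 5 and 4 turned in these settings, each time with 1 lower gene that is not named there, which also turned on centred Alexa 647 arrays. Rxra was -1.76 with Alexa 647 alone, -1.10 with it centred and -1.98 with it without 4.5 dpc. Camera over the gene lists and the region and co-variation tests stayed above 0.05 in every setting run, with the lowest adjusted p of camera, 0.0513, for the pharyngeal list with Alexa 555 alone.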

Other observations

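The tests of the sign of swapped arrays, of a constant dye bias, of the 4.5 dpc array in Alexa 647 and of the genes below the reference on Alexa 647 arrays were chosen only after the results were seen, as were the simulated bar for the partners of genes at the level of the empty spots and their test in early and late stages apart; those of the splits and of neighbouring genes were set before. Neighbouring genes of the deleted region were tested for varying together. Over 17 adjacent pairs of the genes matched by name the mean correlation of stage profiles was -0.128. This was below the median of 0.098 in random gene orders (one-sided permutation p = 0.996 for a higher value). It was thus lower than in nearly all random orders, but no test for a lower value had been set. With the embryo in Alexa 647 alone the mean correlation was 0.030 against 0.131 (one-sided permutation p = 0.874 for a higher value).

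Profiles of 2 genes, chosen after their values were seen, are given for both dye orientations. Serpind1, a product of the liver, lay in order of stage at 0.37, -4.47, -3.25, -4.45, -2.13, -1.40 and -0.18 with the embryo in Alexa 647, inside the range of the empty spots at 4.5 and 9.5 dpc. In Alexa 555 it lay at -1.12, 0.54, -1.68, 1.27, -0.76, 0.09 and -0.21. Crabp1 lay at -0.98, 0.38, 0.32, -0.59, 1.73, 2.28 and 2.44 in Alexa 647, and in Alexa 555, inside that range throughout, at 1.55, 1.52, 1.64, 1.60, 0.82, 0.49 and 0.74.

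Chance could not be excluded for the early and late groups: 3 of the 35 splits of the 7 stages into 4 and 3 gave at least the 4 genes seen, and the highest other split gave 9. That split sets 6.5, 7.5 and 8.5 dpc against the rest, which is also how the arrays with the embryo in Alexa 555 cluster. Whether this is a structure of the samples or of these arrays was not tested. No blocked value bears on the early and late groups, since within these clusters 4.5 dpc is the only early stage that can be set against late ones. For the pharyngeal stages all 35 splits gave at least the 0 genes seen, and the highest other gave 9. For the slope all 100 stage orders drawn gave at least the 0 genes seen, and the highest other gave 3; any split meets a count of 0, so neither test says more.

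The weak correlation of swap partners may come in part from genes without a ratio of their own, since it was higher by 0.425 outside the range of the empty spots than inside it (95% bootstrap interval over genes 0.150 to 0.656). Picking pairs by their own ratios gives part of this: simulations of 1 correlation for all genes of a stage gave a median of 0.115 and an upper end of the 95% range of 0.396. The early stages gave 0.769 (interval 0.482 to 0.980) against 0.347 and 0.668 in simulations, and the late ones 0.018 (interval -0.386 to 0.449), which leaves it open there. A constant dye bias of each gene stays open: taking it off moved the correlation by 0.010 (interval -0.093 to 0.115), but this also takes off the level the orientations share, and constant opposite offsets had a variance over genes of 0.178 (interval 0.111 to 0.247), which would be shared levels with no change of sign. Whether swapped arrays were deposited without a change of sign stayed open too: the stage deviations of partners correlated at -0.109, lower than in most of the 5040 orders but not past the threshold (one-sided exact permutation p = 0.074). No biological explanation was tested, because the partners were taken to share their RNA.

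The 4.5 dpc array with the embryo in Alexa 647 correlated with the other 6 at -0.06 to 0.15 over genes, where those correlated with each other at 0.26 to 0.86. A shuffle of all rows is argued against, since its 8 ratio control probes correlated at 0.965 with the mean of the other 6 Alexa 647 arrays. These probes cannot show a shuffle among the gene rows alone. On the arrays with the embryo in Alexa 555 the same correlation was 0.97 at 7.5 dpc but 0.08 to 0.62 at the other stages. Whether rows are shuffled there was not tested. Gene signal at the level of the empty spots is a candidate explanation, with 61 genes inside their range against 17 to 34 on the others. On this array, though, that range went from -0.996 to 1.606, so expressed genes near the level of the reference also lie inside it. Embryos of the earliest stage may also truly differ: the 4.5 dpc array of the other orientation did not stand apart, with a mean correlation of 0.253 against a median of 0.227 for the other 6, but the gap is smaller than their spread. Without a margin for spread, which was set after that value was seen, it would have counted against this explanation.

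With the embryo in Alexa 647, 35 genes lay below the reference and 0 above, but 14 below and 11 above with these arrays centred, so the one-sided count depends on the level of the arrays. Of the 35, 21 lay inside the range of the empty spots on at least 4 of the 7 arrays, and 0 of the other 31 did. The 35 were called for their low ratios, and from 6.5 dpc on the empty spots were low too, with medians of -3.44 to -1.56. This contrast is therefore largely fixed by the selection and does not bear on the cause. The ratios of the 35 genes may follow the background: over 6 arrays their median correlation with the empty spots was 0.213 above that of the other genes, which permutation of gene labels did not set apart (p = 0.119). Lower expression than in the 18.5 dpc pool stays open too, since on the arrays with the embryo in Alexa 555 the same genes differed from the others by 0.035 after the change of sign (permutation p = 0.855), and the comparison would turn its sign with that change left out.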
